A study of Glycine max with 12 samples.

How the data were processed

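Messenger RNA was measured by short-read sequencing in 12 libraries of soybean (Glycine max), cultivar Williams 82, with 1 library for each stage or organ. Per the labels, 7 libraries came from whole seeds: globular (0.8 to 1.1 mm long), heart (2 to 2.5 mm), cotyledon (3 to 3.9 mm), early maturation (6 to 7 mm), mid maturation (1.1 to 1.3 cm), late maturation (1.2 to 1.5 cm) and dry seed. The other 5 came from trifoliate leaves, roots free of nodules, stem internodes, unopened floral buds and whole seedlings 6 days after imbibition. No group had a second library, so no spread between replicates exists and no test of a difference between stages or organs was made.

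For 10 libraries the authors deposited the raw number of reads mapped to each gene model, which is the unit count here. The same 66210 gene models stood in the same order in all 10. Reads were aligned with Bowtie, per the submitters' processing notes. For the mid- and late-maturation libraries the authors deposited RPKM (reads scaled by gene length and library size) for genes above 0 only, and Bowtie and bedtools were used, per the submitters' processing notes. Tool versions, genome build, annotation release and the handling of reads that match several places are not given in the sources used here. The mid- and late-maturation libraries were added to the series later and, per the labels, involved a second sequencer model. These 2 libraries therefore form a batch of their own, with other processing, another unit and another set of gene models: 8414 of their identifiers ended in a digit other than 0, which none of the count files used.

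The gene models carry locus identifiers in which the digits before the letter g give the chromosome by naming convention. None of the 74818 identifiers matched the table of gene names used here (assembly Glycine_max_v4.0, 59048 genes), so names could not be looked up. The genes named in the text are 17 loci whose published assignments were listed before the data were examined, in 4 lists: 10 seed storage proteins, 2 protease inhibitor and lectin genes, 1 oleosin and 4 seed regulators. These names are published locus assignments, they were not checked against sequence here, and no coordinates were used. Wider lists based on gene descriptions could not be applied. The rule fixed beforehand named the list members and, for each comparison, the genes with the largest changes. Without names, at most 2 identifiers that rose and 2 that fell were printed for a comparison. Several storage protein genes have near-identical copies (Gy1 and Gy2, and the alpha and the beta copies of beta-conglycinin), so the division of reads between copies is uncertain.

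Counts were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3 and expressed as CPM, counts divided by the effective library size in mega-counts (M). A gene was called higher or lower when 2 libraries differed by at least 4-fold, with counts under 3 set to a floor of 3, and the higher library had at least 10 CPM. Each fold of a named gene carries the exact (Clopper-Pearson) 95% interval of the conditional binomial for its 2 counts. Where a library had 0 counts the fold was computed against 3 counts and is given with the lower end of its 95% interval. These intervals and floors cover counting error only, since amplified reads are not independent molecules, and they hold nothing about variation between plants. List members counted as measured when their mean over the 2 libraries was at least 1 CPM or 1 RPKM. For lists with at least 5 measured members the median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. RPKM values were compared as log2(RPKM + 0.5), with calls at 4-fold and at least 5 RPKM in the higher library. Folds on this scale understate the change of low genes. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

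Because deposited RPKM values of low genes are whole multiples of the worth of 1 read, the depth behind them could be recovered: 59542387 reads for mid maturation and 103601188 for late maturation. At these depths, 87.3% and 88.1% of the 1500 lowest values tested came out as whole reads for a gene of whole-number length, within a tolerance of 0.03. Gene lengths were recovered in the same way (median 1441 nt), and 35568 genes then had counts, RPKM and a length. With these lengths, RPKM was computed from the counts of the other 10 libraries to set them beside the mid- and late-maturation libraries. A recovered length can be too small by a whole factor. On simulated data with 44173 genes the depth was recovered exactly for both libraries, a length was found for 99.9% of genes and was exact for 89.2% of those, and 10.6% were too small by a whole factor. RPKM computed from counts is too high for a gene whose length came out too small. The simulation did not cover gene models that differ between the batches. Its reads and lengths also started from the recovered ones, in which shared whole factors had already been divided out. The percentage of lengths that are too small can therefore be higher in the real data. The rule for calls was tested on simulated counts for each of the 5 steps between count libraries, over 66210 genes with 200 genes changed by 8-fold: 100% of the changed genes were called in each step, and 0 unchanged genes. The simulation held counting noise only, so it checks the computation and says nothing about false calls from amplification or from variation between plants.

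Library totals ran from 10.3 M counts in stem to 45.7 M in globular seed, so that 3 counts corresponded to 0.291 CPM in stem and 0.0656 CPM in globular seed, without TMM scaling. Alternatives fixed before the data were examined were plain CPM, size factors from DESeq2 1.42.0, no minimum level, a minimum of 50 CPM, a 2-fold threshold, a call only when the whole counting interval lay past 4-fold, pseudocounts of 0.1 and 1 RPKM, RPKM rescaled by the median ratio between libraries, detection at 3 counts and detection after thinning to the smallest total. Alternatives added after the data were seen were the subtraction of an early-maturation share from the globular library, leaving out the dry seed library or genes with a recovered length under 1000 nt (with and without rescaling), DESeq2 size factors and rescaled RPKM applied to the gene lists, and every other scaling applied to the named loci.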

Results

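Transcripts of soybean were counted in 12 libraries, each from 1 stage or organ of cultivar Williams 82. The series follows seeds from the globular embryo to the dry seed and sets them beside seedling, leaf, root, stem and floral bud. The 10 libraries with counts held 45.7 M (mega) counts (globular), 22.0 M (heart), 25.2 M (cotyledon), 38.2 M (early maturation), 21.5 M (dry), 18.6 M (seedling), 23.3 M (leaf), 20.2 M (root), 10.3 M (stem) and 32.3 M (floral bud). The RPKM values of the mid- and late-maturation libraries implied 59.5 and 104 M reads. Every difference below is between 2 single libraries, so none has a replicate check and no p-value is given.

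Of all gene models, 54644 had at least 1 count in some library and 19631 reached 1 CPM in all 10 count libraries. Of these 10, the dry seed had the fewest genes at 1 CPM or more, 23608, against 31447 in globular seed, 31505 at early maturation, 34250 in seedling and 35612 in floral bud, which had the most. At 1 RPKM or more, another unit on another set of gene models, mid maturation had 25681 genes and late maturation 23070. The 10 most abundant genes took 11.3% of the counts in dry seed (95% exact binomial interval 11.3 to 11.3%), 7.57% at early maturation (7.56 to 7.58%) and 2.67% in floral bud (2.66 to 2.67%). In the mid-maturation library the 10 most abundant genes made up 38.8% of the sum of RPKM, and in the late-maturation library 14.5%. The alpha-prime subunit of beta-conglycinin was the most abundant gene at early maturation, with 13497 CPM before TMM scaling.

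Across 42154 genes, log2(CPM + 1) of neighbouring seed stages was most alike between heart and cotyledon (Pearson r = 0.976, Spearman rho = 0.975), followed by globular and heart (0.944 and 0.945). The dry seed had r of 0.498 with root and 0.592 with early maturation, the lowest and highest of its 9 values. Seedling was closest to stem (r = 0.845), and leaf to floral bud (r = 0.843). On the RPKM scale over 33473 genes, mid maturation was closest to early maturation (r = 0.824), and late maturation to dry seed (r = 0.890). These correlations are across genes, which are not independent replicates.

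**Figure D1:**
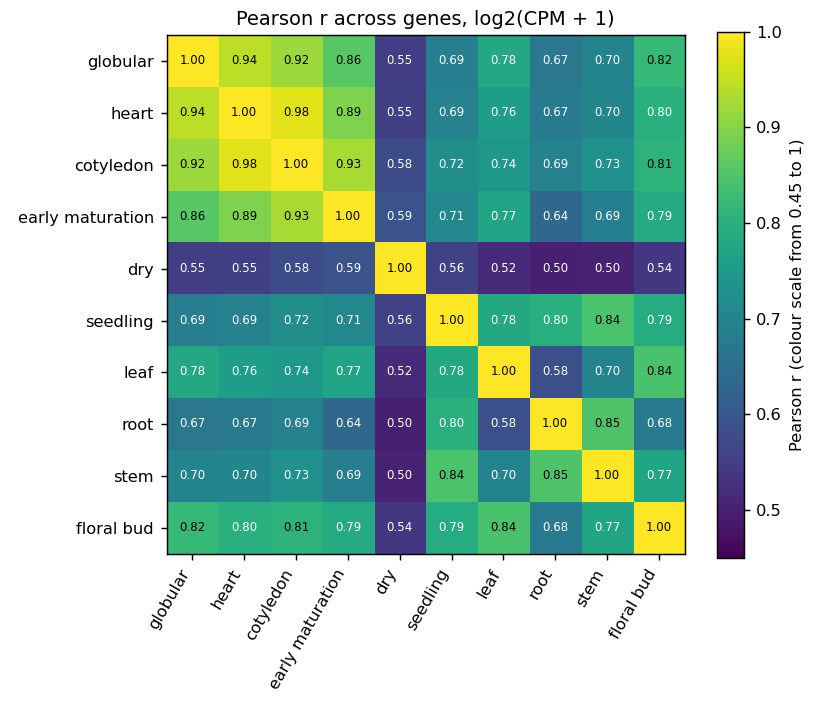
Pearson correlation across 42154 genes of log2(CPM + 1) for each pair of the 10 count libraries, with the value printed in each cell. The dry seed row lies between 0.498 and 0.592, while the cell for heart and cotyledon is at 0.976.

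From the globular to the heart stage, transcripts of the seed regulators rose. LEAFY COTYLEDON1 (LEC1), a subunit of a transcription factor needed for embryo maturation, has 2 homologs in the list. Glyma07g39820 went from 0.702 to 12.3 CPM, which is 17.6-fold (95% counting interval 12.4 to 25.7). ABSCISIC ACID INSENSITIVE3 (ABI3), a transcription factor of the abscisic acid response in seeds, also has 2 homologs, and both rose: Glyma08g47240 by 25.3-fold (18.2 to 36.2) to 19.3 CPM and Glyma18g38490 by 45.6-fold (26.8 to 84.4) to 12.8 CPM. The remaining LEC1 homolog, Glyma17g00950, stood at 40.8 times its globular level (22.3 to 82.9) with 215 counts in heart, and just missed the minimum of 10 CPM. Thus 3 of the 4 measured regulators were called higher and none lower. No storage protein gene was called in this step. Those measured were low in both libraries: Gy1 had 4.76 CPM in globular and 0.0837 in heart seed, Gy2 2.41 and 0.0418, and the alpha-prime subunit 8.73 and 1.42. Across 29 genes that exceeded 200 CPM at early maturation and lay at 0.5 CPM or less in heart, the globular library held a median of 7.13 CPM for each 10000 CPM in the early-maturation library, with quartiles of 6.46 and 8.34. Gy1 and Gy2 are among these 29 genes. The alpha-prime subunit is not, because heart held 1.54 CPM of it before TMM scaling. Its 9.51 CPM in globular seed and 13497 CPM at early maturation, before TMM scaling, lie close to that share. Applied to the regulators, the share would cover the whole globular level of Glyma17g00950, 0.241 CPM against 422 CPM at early maturation on that scale. It would cover part of the globular level of the other regulators, so their folds may not measure the rise alone.

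Over all genes, 451 were higher and 256 lower in heart than in globular seed, which together are 2.23% of the 31679 measured genes. Glyma03g04390 on chromosome 3 rose most, from 5 counts to 73.7 CPM, followed by Glyma17g09110 on chromosome 17, from 0.401 to 279 CPM. The deepest falls were those of Glyma06g02420 on chromosome 6, from 48.5 to 0.0837 CPM, and Glyma03g04670 on chromosome 3, from 36.3 to 0.126 CPM. At a 2-fold threshold the majority turned, with 1324 genes higher and 1500 lower. With the early-maturation share taken off the globular counts, a setting chosen after seeing the data, 454 genes were higher and 256 lower.

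From heart to cotyledon stage the regulators rose further. Glyma17g00950 (LEC1 homolog) reached 52.8 CPM, a rise of 5.87-fold (5.08 to 6.80), and the ABI3 homologs Glyma08g47240 and Glyma18g38490 rose 5.62-fold (5.09 to 6.21) and 4.66-fold (4.12 to 5.28). Glyma07g39820 stood 3.49 times higher (3.07 to 3.97), under the threshold. Again 3 of 4 were called higher. Among storage proteins, only the alpha-prime subunit of beta-conglycinin was measured: it rose 13.4-fold (9.47 to 19.5) to 19.1 CPM. The seed lectin LE1, a carbohydrate-binding protein of the seed, rose 110-fold (37.5 to 538) from 3 counts to 13.9 CPM. Oleosin P24, a coat protein of oil bodies, stood at 0.167 and 3.67 CPM and was not called. This was the step with the fewest calls, 174 higher and 37 lower, or 0.664% of the 31786 measured genes. LE1 was exceeded in its rise by Glyma04g08220 on chromosome 4 alone, which went from 0.126 to 19.6 CPM. Glyma09g07340 on chromosome 9 fell most, from 29.6 to 1.48 CPM.

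From cotyledon stage to early maturation the storage protein transcripts rose steeply. All 7 measured members of the list were called higher, with a median log2 ratio of 12.24, above those of 100% of the random lists. Glycinins and beta-conglycinins are the main storage proteins of soybean seed. Gy1 (Glyma03g32030, chromosome 3) went from 2 counts to 295740 counts, or 8383 CPM. That is 118766-fold (32878 to 980697) without the floor of 3 counts. With the floor its log2 ratio was 16.27, the largest among the genes called in this step. Gy2 (Glyma03g32020) reached 4345 CPM from 5 counts. Gy4 (Glyma10g04280, chromosome 10) was at 0 counts in the cotyledon library, where 3 counts equal 0.106 CPM, and at 2315 CPM at early maturation, so that it was at least 21866-fold higher. The alpha-prime subunit (Glyma10g39150, chromosome 10) rose 767-fold (705 to 836) to 14616 CPM. The members that were not measured were the beta subunit genes Glyma20g28640 and Glyma20g28460, at 0.624 and 0.198 CPM at early maturation, and Glyma20g28660, which had 0 counts in all 10 libraries. Of the 7 measured members, 3 had 0 counts in the cotyledon library and Gy1 had 2, and these entered the median at the floor. The median of 12.24 is the value of Gy5 (Glyma13g18450), which had 0 counts there, so it depends on the floor.

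The lectin LE1 rose 279-fold (253 to 309) to 3875 CPM and oleosin P24 rose 190-fold (157 to 233) to 698 CPM in the same step. Both LEC1 homologs rose, Glyma07g39820 by 6.63-fold (6.25 to 7.05) and Glyma17g00950 by 8.66-fold (8.21 to 9.13), while the ABI3 homologs were 2.70 and 2.94 times higher, under the threshold. Over all genes 617 were higher and 466 lower, 3.35% of 32326 measured. Plain CPM moved the median log2 ratio to -0.28 over measured genes with at least 3 counts in both libraries. The majority then turned to 450 higher and 713 lower. Glyma08g12270 on chromosome 8, next to Gy1 among the largest rises, was at least 64298-fold higher, and Glyma07g04010 on chromosome 7 fell most, from 25.4 to 0.113 CPM.

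**Figure D2:**
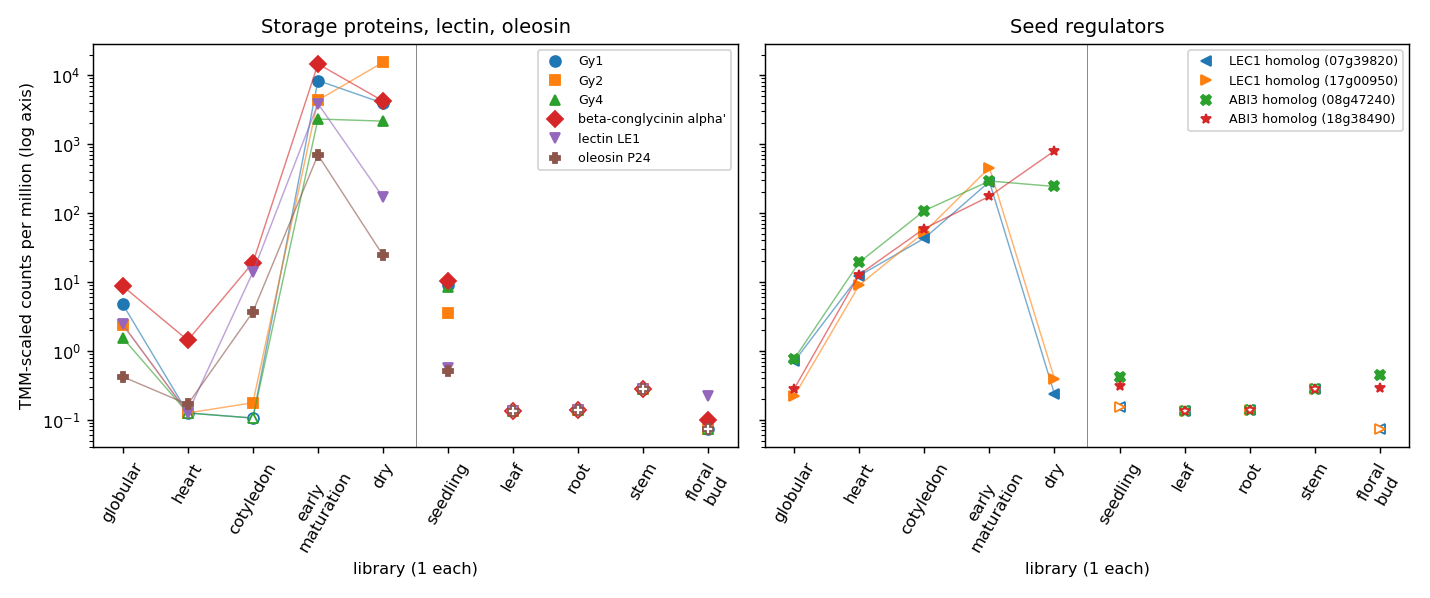
TMM-scaled CPM (log axis) of 10 named loci in the 10 count libraries, with 1 library per point. Lines join the seed stages, and open symbols mark fewer than 3 counts, drawn at the level of 3 counts. The storage protein, lectin and oleosin loci peak at early maturation or, for Gy2 at 15406 CPM, in dry seed. The LEC1 homologs are at 0.236 and 0.393 CPM in dry seed, and the ABI3 homologs at 243 and 801 CPM.

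Between early maturation and the dry seed the LEC1 and ABI3 homologs parted. The LEC1 homologs fell from 285 to 0.236 CPM (1209-fold, 414 to 5866) and from 457 to 0.393 CPM (1162-fold, 498 to 3580). The ABI3 homolog Glyma18g38490 rose 4.58-fold (4.43 to 4.72) to 801 CPM, a call that plain CPM ended (log2 ratio 1.55 against 2.19), and Glyma08g47240 stood at 292 and 243 CPM. Of the 9 measured storage proteins, 2 were called higher, 1 lower and 6 neither. The alpha subunit gene Glyma20g28650 fell from 80.6 to 1.42 CPM (57.0-fold, 36 to 96.2). The beta subunit genes, whose reads may be shared, rose to 38.9 CPM (Glyma20g28640, 62.4-fold, 40.8 to 101) and 43.1 CPM (Glyma20g28460, 217-fold, 105 to 543). Gy1 had 8383 and 3932 CPM, Gy2 4345 and 15406, and the alpha-prime subunit 14616 and 4226 CPM in the early-maturation and dry libraries, each under the threshold. With plain CPM the alpha-prime subunit passed it (log2 ratio -2.43 against -1.79). The list median of -0.10, at percentile 20.9 of the random lists, changed sign with DESeq2 size factors, to 0.07, and has no direction here. LE1 fell 22.8-fold (21.9 to 23.8) and oleosin P24 28.7-fold (25.7 to 32.2).

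This step had 4418 genes higher and 5769 lower, 31.7% of 32161 measured, and 788 of the latter had 0 counts in the dry seed. Glyma01g29480 on chromosome 1 rose from 0.142 to 2642 CPM. Glyma07g28940 on chromosome 7, with 4708 CPM at early maturation, had 0 counts in the dry library and was at least 19951-fold lower. The split depended on the scaling and the minimum level. Plain CPM put the median log2 ratio of measured genes with at least 3 counts in both libraries at -0.59. It gave 2550 higher and 6690 lower, and a minimum of 50 CPM gave 2731 higher and 1595 lower.

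From the dry seed to the seedling 6 days after imbibition, every measured member of the lists was called lower. All 8 measured storage proteins fell, with a median log2 ratio of -8.07, below those of all random lists (percentile 0). Gy2 fell 4331-fold (3422 to 5567) to 3.56 CPM, Gy1 429-fold (370 to 499) to 9.18 CPM, Gy4 259-fold (222 to 304) and the alpha-prime subunit 414-fold (360 to 478) to 10.2 CPM. LE1 fell 299-fold (167 to 601) and oleosin P24 47.2-fold (25.3 to 99.3). Of the seed regulators, 2 were measured and both fell, the ABI3 homologs Glyma08g47240 by 590-fold (299 to 1368) and Glyma18g38490 by 2589-fold (1189 to 7057). The LEC1 homologs, with 3 and 5 counts in the dry seed, had 1 count each in the seedling.

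In all, 6139 genes were higher and 4375 lower in the seedling, 31.2% of 33740 measured, and 1005 of those that rose had 0 counts in the dry seed. Glyma07g01730 on chromosome 7 rose from 0.708 to 8044 CPM, and Glyma18g43320 on chromosome 18 fell from 1431 to 0.206 CPM. Plain CPM put the median log2 ratio of measured genes with at least 3 counts in both libraries at 0.75. It gave 7785 higher and 2103 lower. With a minimum of 50 CPM the majority turned, to 1676 higher and 2860 lower.

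**Figure D3:**
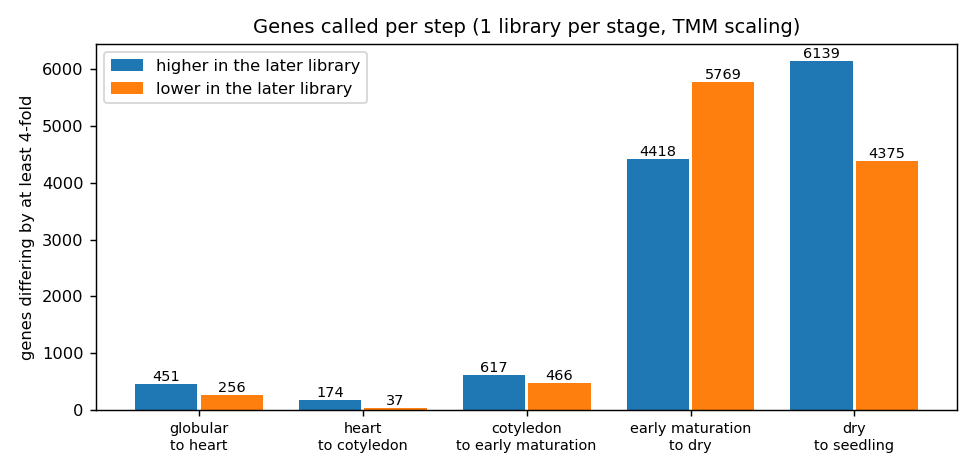
Number of genes that differed by at least 4-fold between successive count libraries, with TMM scaling and at least 10 CPM in the higher library. Bars start at 0 and stand for genes higher or lower in the later library. The heart to cotyledon step has 174 and 37, and the dry to seedling step 6139 and 4375.

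Mid and late maturation were compared on the deposited RPKM of 44202 genes. All 8 measured storage proteins fell, with a median log2 ratio of -4.25 (percentile 0 of the random lists). Gy4 fell from 31302 to 434 RPKM, Gy1 from 27614 to 658, Gy2 from 32999 to 3976 and the alpha-prime subunit from 22703 to 1609. The Kunitz trypsin inhibitor KTI3 (Glyma08g45531, chromosome 8), a protease inhibitor of the seed that was listed in these files only, fell from 20181 to 68.9 RPKM, and the lectin LE1 from 12759 to 126. Oleosin P24 fell from 1483 to 24.8 RPKM. Of the 4 regulators, both LEC1 homologs fell, Glyma07g39820 from 16.3 to 0.122 RPKM and Glyma17g00950 from 65.5 to 1.23, while the ABI3 homologs were not called, at 146 and 117 RPKM (Glyma08g47240) and 95.2 and 167 RPKM (Glyma18g38490). Over all genes 2859 were higher and 1929 lower. After rescaling by the median ratio, which was 0.53 in log2 terms over 20068 genes, 1806 were higher and 3111 lower, so the majority turned, whereas the median of the storage proteins became -4.79.

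**Figure D4:**
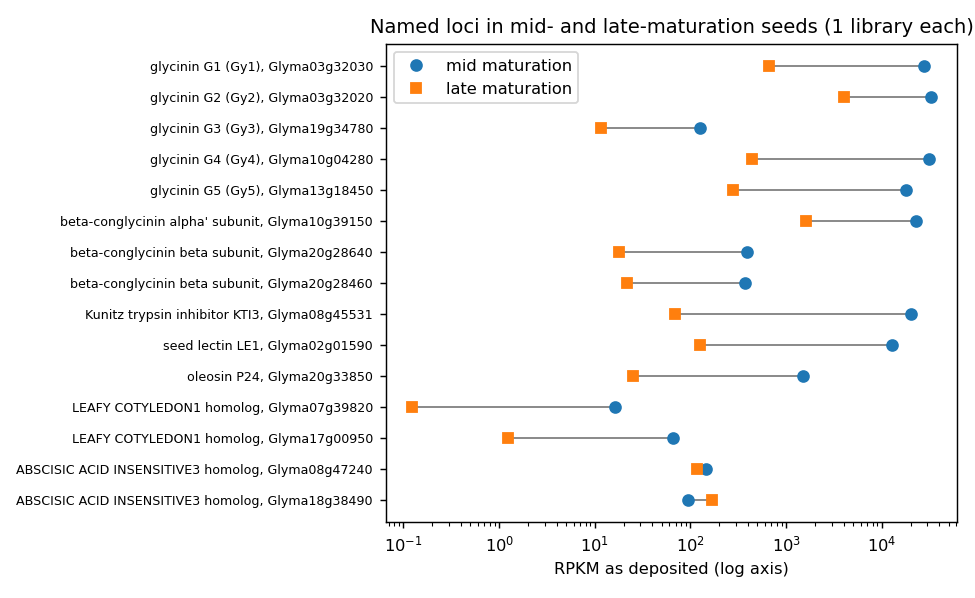
Deposited RPKM (log axis) of the named loci listed in the mid- and late-maturation libraries, with 1 library per point and a line joining both values of a locus. The 11 storage protein, protease inhibitor, lectin and oleosin loci and both LEC1 homologs are lower at late maturation, and the ABI3 homologs lie between 95.2 and 167 RPKM in both.

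The steps into mid maturation and out of late maturation cross the batches, and stage and batch cannot be told apart in either. From early to mid maturation 6 of 8 measured storage proteins were called higher. Gy4 stood at 1076 RPKM, computed from its counts and a recovered length of 1987 nt, and at 31302 RPKM at mid maturation. Gy5 (Glyma13g18450, chromosome 13; 1588 nt) had 299 and 17880 RPKM, and the beta subunit gene Glyma20g28460 (1585 nt) 0.116 and 375. A recovered length that is too small would raise the computed RPKM and so understate these rises. After rescaling by the median ratio Gy1, the alpha-prime subunit and oleosin P24 passed the threshold too (log2 ratios 2.24, 3.02 and 2.29). The LEC1 homolog Glyma07g39820 (1271 nt) had 207 and 16.3 RPKM, and the ABI3 homologs were not called. From late maturation to dry seed 7 of 8 storage proteins and all 3 measured regulators were not called. Gy1, the exception, had 658 RPKM and 3848 RPKM, the latter from a recovered length of 604 nt that can be too small.

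Over 35568 genes 200 were higher and 4727 lower from early to mid maturation, and 1646 higher and 539 lower from late maturation to dry seed. The median log2 ratio was -1.13 in the first of these steps, over 21553 genes with at least 1 RPKM in both libraries, and 0.35 in the other, over 17452. After rescaling by it the counts were 442 and 1388, and 1185 and 902. In the 25921 genes with a recovered length of at least 1000 nt, as deposited, they were 110 and 2085, and 519 and 408, and after rescaling by the median ratio of those genes 252 and 457, and 380 and 558, so that the majority of the latter step turned. Of all genes compared, as deposited, 824 were lower in the former step and higher in the latter, against 219 for independent lists of those sizes, and 62 were higher and then lower, against 3.03. The figures for independent lists count genes too low to be called in either step, so they overstate the excess.

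The seed libraries of the count batch were then compared with the other organs as a whole. In 3392 genes the highest of the 5 seed values was at least 4 times the highest of the 5 non-seed values, and in 4804 genes the reverse held. The seed-preferred genes included 15 of the 17 named loci, namely all those with counts. They took 11% of the counts in globular seed, 16.4% in heart, 18% in cotyledon, 25.4% in early-maturation and 53.7% in dry seed, and between 4.40% (leaf) and 6.66% (floral bud) in the other organs. Of them 2494 had their highest seed value in the dry seed, 382 at early maturation, 245 in heart, 137 in globular and 134 in cotyledon seed. The high shares in seed follow from the choice of genes by their seed values. The dry seed decides the count of genes: without that library, a setting chosen after seeing the data, 980 genes were seed-preferred, and plain CPM gave 1941. How the shares would change without that library was not tested. Genes preferred in non-seed organs peaked in root (1495), stem (1181), leaf (955), seedling (658) and floral bud (515).

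Genes at least 4 times higher in a given library than in any of the other 9 numbered 466 for root, 286 for floral bud, 218 for stem, 191 for seedling and 171 for leaf. Of genes named after their values were seen, Glyma08g08770 on chromosome 8 led in leaf with 16794 CPM, Glyma04g35130 on chromosome 4 in root with 3855 CPM and Glyma14g08380 on chromosome 14 in floral bud with 1737 CPM. Among seed stages the dry seed had 1989 such genes, early maturation 110, globular 21, heart 8 and cotyledon 2, which were Glyma18g47450 (259 CPM) and Glyma01g38390 (74.7 CPM), also named after their values were seen. The early-maturation genes included LE1, oleosin P24, both LEC1 homologs and the alpha subunit gene Glyma20g28650, and the dry seed genes the ABI3 homolog Glyma18g38490 and both beta subunit genes. The other 9 leave out the mid- and late-maturation libraries. On the RPKM scale, across the batches, the beta genes had 394 and 375 RPKM at mid maturation against 27.6 and 16.1 in dry seed. Glyma18g38490 had 167 RPKM at late maturation and 321 in dry seed, and oleosin P24 1483 at mid and 666 at early maturation. Both LEC1 homologs were lower at mid than at early maturation. Plain CPM gave 859 genes for dry seed, 109 for leaf and 4 for cotyledon seed.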

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

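Settings called added were chosen after seeing the data. Plain CPM, DESeq2 size factors and the counting interval kept the number of called genes in each count step within 1.5 times the reported one, as did both pseudocounts and the absence of a minimum in each RPKM step. In the order globular to heart, heart to cotyledon, cotyledon to early maturation, early maturation to dry and dry to seedling, no minimum gave 3536, 1188, 3284, 18126 and 19393 called genes, a minimum of 50 CPM 197, 42, 415, 4326 and 4536, and a 2-fold threshold 2824, 1041, 4230, 15470 and 15990. Looser or stricter criteria move these counts by construction. From early to mid maturation rescaling gave 1830. Genes of at least 1000 nt (added) gave 2195 there and 927 from late maturation to dry, over fewer genes, and 709 and 938 when also rescaled (added).

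Plain CPM gave 1941 seed-preferred and 988 stage-preferred genes. No minimum gave 8451 non-seed-preferred and 2555 organ-preferred genes. The 2-fold threshold gave 7884 seed-preferred, 7518 non-seed-preferred, 3765 organ-preferred and 5150 stage-preferred genes. Without the dry seed (added) 980 were seed-preferred. Detection at 3 counts or after thinning stayed within 1.5 times in all 10 count libraries.

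Medians of gene lists moved past their counting intervals with plain CPM: storage proteins to 11.96 (cotyledon to early maturation), -0.74 (early maturation to dry) and -7.25 (dry to seedling), and seed regulators to 1.86, -5.87 and -9.45 in those steps. The list interval behind the 11.96 held no error for counts of 0, and its median was that of Gy5, with 0 counts in cotyledon seed. The interval of Gy5 itself, 10.70 to 14.52, holds 11.96, so that move is not beyond counting error. Members with at least 10 CPM gave 13.33 for storage proteins from cotyledon to early maturation. DESeq2 factors (added) turned storage proteins from early maturation to dry to 0.071. Rescaled RPKM (added) gave, from mid to late maturation, -4.79 for storage proteins, -7.95 for inhibitor and lectin and -3.07 for regulators; from early to mid maturation 5.57 and -0.79 for storage proteins and regulators; and from late maturation to dry -0.18 and -0.21, both changes of sign. The cause was not tested beyond the scaling itself. No ratio of a called named locus changed sign under any scaling, but that of 3 uncalled ones did (Gy4 from early maturation to dry with DESeq2 factors, and Glyma18g38490 into mid maturation and Glyma17g00950 out of late maturation when rescaled). Calls changed (scalings of loci were all added) for Glyma18g38490 and the alpha-prime subunit from early maturation to dry with plain CPM (1.55 and -2.43), and for Gy1, the alpha-prime subunit and oleosin P24 into mid maturation when rescaled. Ratios of measured loci moved past the counting interval, or at all for RPKM, which has none here, in 72 cases and not in 78. With 1 library each, depth limits genes near the floor: 3 counts equal 0.0602 TMM-scaled CPM in globular seed and 0.283 in stem.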

Other observations

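The tests of early-maturation transcripts in the globular library, the test of depth in the dry seed and the tests of abundant storage transcripts on short and long genes were chosen, or their readings changed, after the result was seen, and the other tests were fixed before their results were seen. The readings first fixed would have pointed to carry-over into the globular library, to gene models that differ between batches and away from gene lengths. All were changed to undecided after the results were seen, because unrelated libraries met the range set for carry-over, every gene behind the model test had a short recovered length, and the counting spread of the length test was wide.

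In 6 of 12 sets, genes with the same preference lay side by side more often than in any of the shuffled orders. Each set of a single library lies within the seed- or non-seed-preferred set, so the 6 share pairs and are not separate results. Among 29483 genes with at least 10 CPM in some library, taken in the order of their identifiers along each chromosome, seed-preferred genes formed 549 neighbouring pairs, against 353 to 432 in 100 shuffled orders. Non-seed-preferred genes formed 1085 pairs (716 to 847 in shuffled orders), dry-seed genes 232 (105 to 168), root genes 29 (1 to 13), stem genes 19 (0 to 5) and seedling genes 15 (0 to 4). Floral bud genes formed 7 pairs and leaf genes 4, each equal to the highest of its shuffled orders, early-maturation genes 1 (0 to 2), and globular, heart and cotyledon genes 0. Neighbouring genes of 1 family can share reads, which was not tested here.

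With the main scaling, the alpha-prime and beta subunit genes of beta-conglycinin were called higher in different steps and lower in the same ones. This contrast depended on the scaling. When rescaled, the alpha-prime subunit was also called higher from early to mid maturation, like both beta genes (log2 ratio 3.02 against 1.89). With plain CPM it was called lower from early maturation to dry (-2.43 against -1.79), where both beta genes were higher. At early maturation the alpha-prime subunit had 14616 CPM and the beta subunit genes Glyma20g28640 and Glyma20g28460 had 0.624 and 0.198 CPM. At mid maturation the deposited values were 22703, 394 and 375 RPKM. In the dry seed they were 4226, 38.9 and 43.1 CPM. Gy3 (Glyma19g34780, chromosome 19) remained the lowest glycinin, with 12.9 CPM at early maturation, 125 RPKM at mid maturation and 29.3 CPM in the dry seed. How reads of near-identical copies were divided is not given in the sources used here.

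Transcripts abundant at early maturation were found in the globular library in nearly constant proportion. Over the 29 genes above 200 CPM at early maturation with 0.5 CPM or less in heart, the SD of the log2 ratio of globular to early-maturation counts was 0.35, which argues against transcription of each gene at a level of its own; the SD was 3.80 for the cotyledon and 2.47 for the seedling library. For these genes the log2 counts in the globular and early-maturation libraries had r = 0.975 (95% Fisher interval 0.947 to 0.988). The other 8 libraries had -0.159 to 0.107, but heart was capped by the choice of genes, and leaf, root and stem had median shares of 0. The r of 0.975 argues against reads shared with paralogs active in globular but not in heart seeds. Genes sharing reads with paralogs active in heart seeds were left out by the choice of genes, so for them the test cannot decide. A carry-over of early-maturation reads, RNA or older seeds into the globular library stays open. Another 20 genes, at 50 to 200 CPM, did not decide it: their median in the globular library was 7.81 per 10000 where the 29 had 7.13, but leaf had 7.94, root 7.75 and heart 15.9. Over these 20 genes the SD was 2.51 and r was -0.030. At 7.13 per 10000 such genes would hold less in globular seed than the 0.5 CPM allowed in heart. Their SD and r could therefore not show a constant share.

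The dry seed had the fewest detected genes of the 10 count libraries. With all count libraries thinned to the total of stem, 29782 genes had at least 3 counts in dry seed and 36483 in globular seed, the next lowest, so dry seed lay 18.4% lower and depth is argued against. With the 100 most abundant genes of each library left out and the rest thinned to 1 total, 24950 and 31574 genes had at least 1 CPM, a gap of 21.0%, so a few abundant genes are not the whole cause either. RNA quality and the stage itself could both lower the number and were not tested.

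Genes lower from early to mid maturation and higher again from late maturation to dry seed numbered 308 after each step was rescaled by its median ratio, where independent lists would share 46.2, and 128 did the reverse, against 11.2. Of the 308 genes 98.1% had a recovered length under 1000 nt, against 27.1% of all genes compared; among genes of at least 1000 nt rescaling by the median ratio of those genes alone took the number from 83 (41.7 for independent lists) to 11 (95% Poisson interval 5.49 to 19.7; 6.70 for independent lists), while 58 did the reverse, against 5.42. Under 1000 nt lay 302 of the 308 genes (95% Poisson interval 269 to 338), against 90.9 for independent lists. All figures for independent lists here count genes too low to be called in either step, so they are too small to judge the excess by. A lowering shared by all other transcripts would be removed by rescaling and would not single out short genes. The 302 short genes left after rescaling therefore argue against abundant storage transcripts as their cause. For longer genes, which rescaling took from 83 to 11, that cause stays open. Lengths recovered too small could cause the fall and rise of short genes, as could a lower yield of short transcripts in the later batch, which was not tested, and the tables do not decide between them. Gene models that differ between the batches stay open too: 9 genes were at 20 RPKM or more in all 10 count libraries and under 1 RPKM in both later ones, where the highest of 45 pairs of count libraries had 3, but all 9 had recovered lengths under 1000 nt.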
